A study of Mus musculus with 6 samples.

How the data were processed

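Whole uteri were profiled on one-colour (Cy3) Agilent arrays, 6 in all. 3 arrays carried RNA from control females with the Wnt7a-Cre transgene alone, and 3 carried RNA from littermates that also overexpressed progesterone receptor A (PGRA) in the uterine epithelium. Per the labels' protocols, females of 8 to 10 weeks were mated with vasectomized males and killed 4 days after a plug was seen. Each array held RNA pooled from 3 mice, so that 9 mice stood behind each genotype. The sample labels also call the tissue natural pregnancy at day 4.5, which does not match mating with vasectomized males, and the sources used here do not settle which holds. The labels' protocols give 25 ng of total RNA, mixed with spike-in RNA, as the input to labelling and 600 ng of labelled cRNA as the amount fragmented. Replicate numbers follow the order of the samples and pair nothing.

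The deposited scanner files hold spot intensity on a linear scale. Per the file headers, Agilent Feature Extraction 11.0.1.1 subtracted the background and removed spatial trends to give a processed signal, whereas the submitters' processing notes name version 9.1. Each deposited value table column is in log2 units and ranks the probes of its array in the same order as the processed signal (Spearman 1.0). All 6 columns share a median of 5.567, so the authors' values behave as quantile-normalized log2 intensity without centring on genes. No source used here states that step. Every array had 62976 spots, 59305 of them not controls, and no spot was marked as saturated. The processed signal at the 75th percentile was 570.2, 593.5 and 565.6 on control replicates 1 to 3 and 510.6, 477.9 and 474.1 on PGRA replicates 1 to 3. Between 58.9% and 66.4% of probes were well above background. The quality verdict in the file headers was to evaluate control replicate 1, and in range for the other arrays. Control replicate 1 also had the most outlier spots (187) and the largest spread of repeated spots (8.12%). For arrays, their number limits the precision. All 6 arrays came from 1 slide and 1 scan. The controls lay in slide row 1 and the PGRA arrays in slide row 2, so slide row and genotype cannot be told apart.

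The files pair probes with accessions but with no gene names. Names were taken from a RefSeq gene table of assembly GRCm38.p6 by accession without version. It named 26582 of 55681 probes, for 20145 genes, and left 29099 probes unnamed. No coordinates are given because the array was designed on another build. Control spots and population outlier spots were left out and spots of one probe were averaged. The measure was log2 of the processed signal minus the array's 75th percentile of it, given here as log2 units. A probe was tested if it was well above background on all 3 arrays of at least 1 group, and each gene was represented by its probe with the highest mean over the 6 arrays. This left 34520 probes and 15210 named genes. The mean used to choose a gene's probe takes in the PGRA arrays. Among probes of similar mean the choice therefore favoured the one reading higher in PGRA, as for Pgr and Calca. Where the tested probe was not well above background on any array of a group, the difference is given as a bound: the brighter group's mean against the dimmer group's mean of, per array, the higher of the probe's own value and the lowest signal among probes well above background. SEs, adjusted p and bounds stand beside both group means in the tables behind the text.

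Genes were tested with limma 3.58.1 (lmFit and eBayes, two-sided, genotype only) in R 4.3.3, with Benjamini-Hochberg adjustment at 0.05. The fit gave 6.41 degrees of freedom per gene, and 5.41 for the 20 genes with a missing array. Gene lists, 39 in number, were fixed before the data were examined, as were the tests, the alternatives and the rule for naming genes. They were tested with limma's camera at a preset correlation between genes of 0.01, two-sided and adjusted over the 39 lists, and again with an estimated correlation and with fry. 20 genes with a missing value on some array were left out of the list tests. The rule named Pgr. It also named the 10 largest rises and 10 largest falls among genes past the threshold without overlap between the groups, up to 5 passing members of the progesterone, estrogen and receptivity lists with their 3 brightest members that did not pass, and up to 4 passing members of every other list. Genes outside this rule were chosen after their values were seen: Sgk1, Slc26a6, Kcnq1, Lgr5, Wnt7b, Reg3g, Cd55, Ttr, Foxa2, Cxcl15, Ltf, Muc1, Cyp26a1, Lif, Msx1, Hhip, Gli1, Mrc1, Xbp1, Mki67, Rrm2, Hba-a1, Alas2, and those of the closing parts. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 read the files and drew the figures.

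The gene and list tests were run on simulated data, for PGRA against control on 15190 genes, 200 of them changed. Means were those of the real genes, and SDs were drawn from limma's fitted distribution of variances. At 2-fold, 70.1% of 67 changed genes were recovered, at 4-fold 91.0% of 67 and at 16-fold 98.5% of 66, all with the right sign, with 11 calls on genes not changed. No gene and no list was called in unchanged data. Simulated genes were drawn independently of each other, so this cannot show how often a list of correlated genes is called without a change. Each simulated gene also had 1 SD for all 6 arrays, whereas real genes had a median SD of 0.181 in controls and 0.105 in PGRA. The simulation therefore cannot show recovery or wrong calls where 1 array stands apart. A shift of a whole list by 1 log2 unit was recovered.

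The alternatives were normexp background correction (offset 50), quantile normalization, scaling to the median, no filter and a stricter filter on dim probes, the authors' value table, the mean of a gene's probes, outlier spots kept, an intensity trend with robust variance, array weights, each array left out, an ordinary test per gene, a 1.5-fold threshold, and the other list tests. Normexp was run on the median signals because the files hold no mean signal. Slide or scan as a block could not be fitted with 1 slide and 1 scan. Slide column as a block, a test of named and unnamed probes together, and counts of list members without control replicate 2 were added after seeing the data.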

Results

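The series asked how excess progesterone receptor A in the uterine epithelium changes the endometrium at the time of receptivity, when the uterus prepares for embryo attachment. Gene expression was measured in whole uteri on 6 arrays, 3 for control mice and 3 for mice overexpressing PGRA in the epithelium. Each array held pooled RNA of 3 mice, so n = 3 below means 3 pools and the spread is that between pools. Levels are in log2 units relative to the array's 75th percentile of signal. Correlations between arrays across genes were 0.992 to 0.994 within the PGRA group, 0.981 to 0.995 within the control group and 0.963 to 0.982 between the groups. Genes are not independent replicates in these correlations. Control replicate 2 stood apart from the other controls, at -51.7 on the first principal component (59.8% of the variance) and -29.4 on the second, against -19.4 and 28.8 for control replicate 1 and -23.2 and 18.9 for control replicate 3.

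Pgr, the overexpressed gene, was higher on every PGRA array by one of its probes and not by the other. With the probe used for the gene, the level was 0.79 ± 0.16 (SD, n = 3) in controls and 3.85 ± 0.12 (SD, n = 3) in PGRA uteri, a difference of 3.06 ± 0.12 (SE) or 8.34-fold (limma, Benjamini-Hochberg adjusted p = 2.91e-04). The second Pgr probe read 2.24 ± 0.27 and 2.30 ± 0.09 (SD, n = 3 each), a difference of 0.06 ± 0.15 (SE) with an adjusted p of 0.892 over all probes in limma. Which of the Pgr transcripts each probe matches was not analysed here, and a probe outside the transgene's transcript checks nothing. With the mean of both probes as the gene's value the difference was 1.56. The array cannot tell receptor isoform A from B.

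Of 15210 genes tested, 520 (3.42%) differed between PGRA and control uteri, with 206 higher and 314 lower in PGRA (limma, Benjamini-Hochberg adjusted p below 0.05). At least 2-fold differences, taken as bounds where a group was below background, were seen for 119 of the genes that rose and 184 of those that fell. The 10 rises and 10 falls named next are the largest by fitted difference, which ranks values below background too, so their order is not that of measured folds. Of the 10 rises, 2 were measured above background in both groups. Pga5, a pepsinogen, rose 28.7-fold from -0.73 ± 0.76 to 4.12 ± 0.24 (SD, n = 3 each). Drd4, a dopamine receptor, rose 25.8-fold. The others were not well above background on any control array, so that their rise is a bound. Gp2, a membrane glycoprotein of zymogen granules, rose at least 26.0-fold, Kynu, the kynureninase of tryptophan breakdown, at least 13.0-fold, and Svs2, a seminal vesicle protein, at least 12.6-fold. The bounds were at least 10.8-fold for Atf7ip2, 10.7-fold for Tnfsf11 (RANKL, a known progesterone target in the mammary gland), 9.86-fold for Pate6, 6.90-fold for Abo (the ABO blood group glycosyltransferase) and 5.42-fold for Pate4.

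The largest fall, by measured fold as well, was that of Spink1, a trypsin inhibitor, by 119-fold from 7.52 ± 0.42 to 0.63 ± 0.73 (SD, n = 3 each; limma, Benjamini-Hochberg adjusted p = 7.69e-04). Prss29 and Prss28, serine proteases of the uterine glands, fell 72.1-fold and 47.6-fold. Aqp5, a water channel, fell 55.2-fold and Atp6v0d2, a subunit of the vacuolar proton pump, 35.3-fold, both well above background on 2 of the 3 PGRA arrays. A second Aqp5 probe, well above background on all 3 PGRA arrays, gave a smaller log2 difference of -4.74 against -5.79. Tmem213 fell 32.3-fold. Below background on all PGRA arrays were Pip, lower by at least 14.7-fold, Fgg, the fibrinogen gamma chain, by at least 11.8-fold, ccdc198 by at least 9.87-fold and Tmprss11a, a membrane serine protease, by at least 9.52-fold. Genes outside the 20 had measured folds above some of these bounds, such as Calca, up 17.9-fold, and Aqp8, down 17.3-fold. Without control replicate 2, 653 genes passed, 289 higher and 364 lower. The number fell to 354 without control replicate 1, to 226 without control replicate 3 and to 295, 244 and 291 without PGRA replicates 1, 2 and 3. Of the 20 genes, Tnfsf11 missed the threshold in 5 of the 6 such fits (adjusted p = 0.0859 without control replicate 3, the highest), Prss28 and Prss29 in 4 each (0.104 and 0.112 without control replicate 3), Tmem213 in 2 (0.0671 without control replicate 3) and Atp6v0d2 in 1 (0.0536 without control replicate 3). With normexp background correction Tnfsf11 (0.0777) and Fgg (0.0525) missed it too. The fall of Prss29 was 30.8-fold without PGRA replicate 1 and 131-fold without PGRA replicate 3, that of Prss28 24.3-fold and 78.8-fold, and that of Aqp5 36.7-fold without PGRA replicate 1 and 85.6-fold without PGRA replicate 2. Atp6v0d2 fell 55.0-fold without PGRA replicate 3 and Tmem213 18.1-fold without PGRA replicate 1. The bound of Tnfsf11 was 21.2-fold without PGRA replicate 1 and that of Fgg 6.83-fold without control replicate 2.

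**Figure D1:**
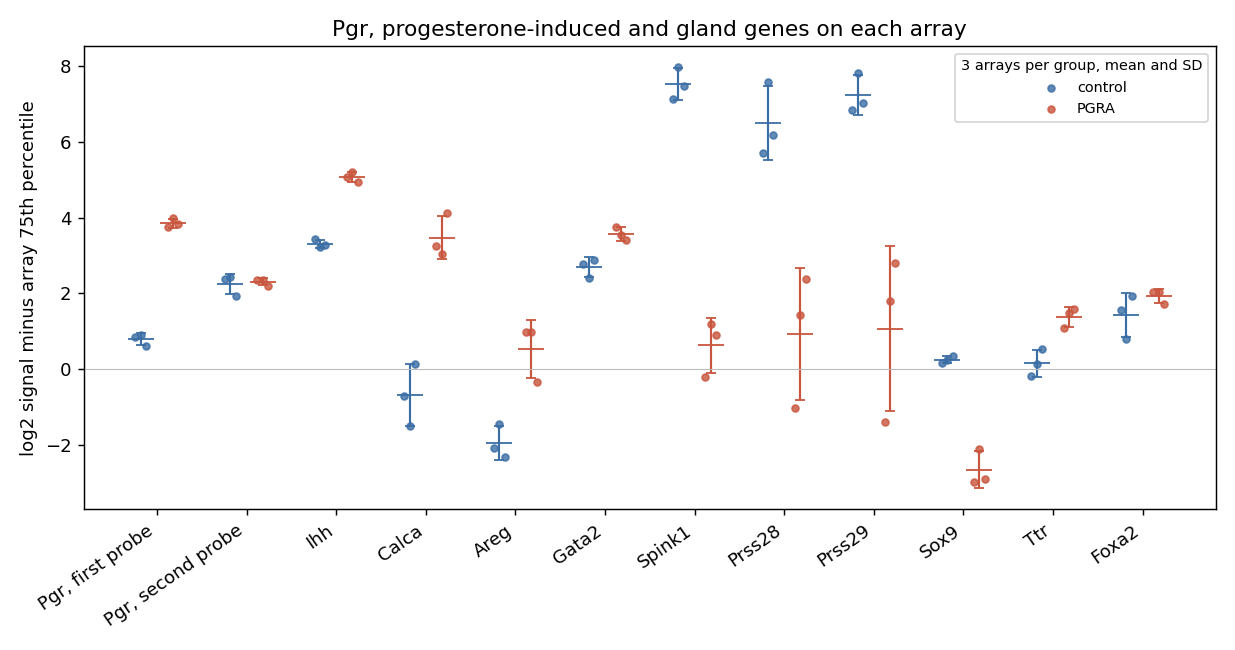
Levels of Pgr (both probes), 4 genes of the progesterone list and 6 of the gland list, in log2 units relative to each array's 75th percentile of signal. Points are single arrays, bars the mean and SD of 3 arrays per group. The first Pgr probe separates the groups by 3.06 while the second reads 2.24 in controls and 2.30 in PGRA, and Spink1, Prss28, Prss29 and Sox9 lie lower on all PGRA arrays.

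Genes known to be induced by progesterone in the uterine epithelium rose as a list. Of 14 tested members 4 rose and 0 fell (6 and 1 when adjusted over the list alone), with a median difference of 0.59 (camera, adjusted p = 1.36e-04). The adjusted p was 0.183 with an estimated correlation. Ihh, the hedgehog ligand through which progesterone acts on stroma, rose 3.39-fold from 3.31 ± 0.10 to 5.07 ± 0.13 (SD, n = 3 each; limma, adjusted p = 0.0010). Calca, which encodes calcitonin, rose 17.9-fold, although another of its probes gave a log2 difference of 1.72 against 4.16. Areg, which encodes amphiregulin, rose 5.62-fold and Gata2, a transcription factor acting with the receptor, 1.83-fold. Members that did not pass included Hdc, the histamine-forming enzyme, at 1.60 ± 0.44 (SE), Fst at 0.18 ± 0.12 (SE), Errfi1 at -0.14 ± 0.13 (SE) and Cyp26a1, a retinoic acid hydroxylase, at -3.55 ± 0.74 (SE; limma adjusted p = 0.0620). Areg missed the threshold in 4 of the 6 fits with an array left out (adjusted p = 0.117 without control replicate 3, the highest), and Gata2 in 5 (0.143 without PGRA replicate 2), as well as with quantile normalization (0.0542), the authors' values (0.0557), unnamed probes included (0.0634) and slide column as a block (0.0799). Hdc passed without control replicate 2 (log2 difference 1.06, adjusted p = 0.0067) and with array weights (1.16, 0.0058), and Cyp26a1 without PGRA replicate 3 (-4.22, adjusted p = 0.0423). Here and below, the array weights rest mostly on control replicate 3 among the controls (8.75, against 0.485 and 0.165 for control replicates 1 and 2). Without PGRA replicate 1 Cyp26a1 stood at -2.74.

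The list of stromal mediators downstream of Ihh shifted upward (camera, adjusted p = 0.0190, and adjusted p = 0.423 with an estimated correlation). 1 of 13 members rose and 0 fell (4 and 0 adjusted over the list alone). The member that rose was Ptch1, the hedgehog receptor and itself a target of the pathway, from 0.15 ± 0.24 to 0.89 ± 0.03 (SD, n = 3 each), 1.67-fold. Gli1 stood at 0.48 ± 0.11 and Hhip at 1.37 ± 0.35 (SE), neither past the threshold. Ptch1 missed it in 5 of the 6 fits with an array left out (highest adjusted p = 0.145 without PGRA replicate 2), with slide column as a block (0.0834) and with unnamed probes included (0.0597). Hhip passed without control replicate 2 (0.0467). The list missed the threshold without control replicate 3 (0.0887), with normexp (0.113) and without the filter on dim probes (0.256). The list of steroid receptors and their coregulators passed with Pgr, the overexpressed gene, among its members (camera, adjusted p = 0.0093, mean 0.24, and adjusted p = 0.638 with an estimated correlation) and not without it (adjusted p = 0.0538, mean 0.11). Of its 22 members Pgr and Greb1 rose and 0 fell (2 and 1 adjusted over the list alone), and its adjusted p was 0.184 without control replicate 2, 0.188 with array weights, 0.0574 with normexp and 0.235 without the filter.

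The receptivity and attachment list as a whole did not pass (camera, adjusted p = 0.574), with a median of 0.05 over 30 members. Ptgs1, a cyclooxygenase, rose 1.66-fold and Areg 5.62-fold, and 0 members fell (2 and 3 adjusted over the list alone). Its brightest members that did not pass were Stat3 at -0.32 ± 0.19, Il6st, the shared LIF receptor subunit, at -0.42 ± 0.11, and Ctnnb1 at -0.15 ± 0.10 (SE, n = 3 each). Lif, the cytokine required for attachment in mice, well above background on 2 of the 3 PGRA arrays, stood at -1.24 ± 0.52 and Msx1 at 1.26 ± 0.43 (SE), also not past the threshold. Il6st passed without control replicate 2 (adjusted p = 0.0308) and with array weights (0.0027), and Lif stood at -0.63 without PGRA replicate 1. Ptgs1 missed the threshold in 5 of the 6 fits with an array left out (highest adjusted p = 0.107 without PGRA replicate 2).

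Genes known to be induced by estrogen in the uterine epithelium fell as a list. Of 14 tested members 4 fell and 1 rose (9 and 2 adjusted over the list alone), with a median difference of -1.23, or -1.17 with members below background at their bound (camera, adjusted p = 0.0012). The adjusted p was 0.204 with an estimated correlation, and 0.0995 without the filter on dim probes. Aqp5 fell 55.2-fold by the probe used for the gene, and less by its second probe. Sprr2f, a small proline-rich protein, fell 5.02-fold and Padi1, a peptidylarginine deiminase, 4.77-fold. Clca1 was at least 2.33-fold lower. Greb1, a coregulator of the estrogen receptor that responds to progesterone as well, rose 1.84-fold from 2.43 ± 0.06 to 3.31 ± 0.10 (SD, n = 3 each; limma, adjusted p = 0.0063). Sprr2a2 (-0.03 ± 0.08), C3 (-0.42 ± 0.16) and Padi2 (0.00 ± 0.27, SE) did not pass, nor did Ltf, which encodes lactoferrin, at -2.44 ± 0.47 (SE; limma adjusted p = 0.0501) or Muc1, a mucin of the luminal surface, at -1.35 ± 0.27 (SE; adjusted p = 0.0586). Ltf passed without control replicate 2 (0.0415) and without PGRA replicate 1 (0.0481), Muc1 without control replicate 2 (0.0155) and C3 with array weights (0.0197). Sprr2f missed the threshold in 4 of the 6 fits with an array left out (highest adjusted p = 0.0920 without control replicate 3). Aqp5 fell 36.7-fold and 85.6-fold without PGRA replicates 1 and 2.

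Markers and secretions of endometrial glands fell as a list, with 4 of 10 members lower and 1 higher (4 and 1 adjusted over the list alone) and a median of -1.40 (camera, adjusted p = 0.0180, and adjusted p = 0.638 with an estimated correlation). Spink1, Prss29 and Prss28 fell as given above, and Sox9, a transcription factor of gland progenitors, fell 7.52-fold from 0.25 ± 0.09 to -2.66 ± 0.49 (SD, n = 3 each; limma, adjusted p = 0.0024). Ttr, which encodes transthyretin, rose 2.34-fold. Foxa2, the transcription factor that marks gland cells, stood at 0.50 ± 0.29 and Cxcl15 at -1.56 ± 0.59 (SE), neither past the threshold with all arrays. Without control replicate 2, Cxcl15 passed at -2.26 (adjusted p = 0.0114). The list's adjusted p was 0.130 without control replicate 1 and 0.118 without control replicate 3, and Ttr missed the threshold in 5 of the 6 fits with an array left out (highest 0.134 without PGRA replicate 2). The luminal epithelium list did not pass (camera, adjusted p = 0.484), with 3 of 16 members lower and 0 higher (5 and 1 adjusted over the list alone). These were Tacstd2, 3.11-fold lower, Wnt7a, the epithelial Wnt ligand, 2.73-fold lower, and Krt7, 1.97-fold lower. Without control replicate 2 the list's camera adjusted p was 0.0172, and 0.566 with an estimated correlation. Wnt7a, Tacstd2 and Krt7 missed the threshold in 1, 4 and 5 of the 6 fits with an array left out (highest adjusted p = 0.104, Krt7 without PGRA replicate 3).

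Complement factors and secreted defence proteins had the smallest adjusted p of all lists (camera, adjusted p = 4.14e-06, and adjusted p = 0.183 with an estimated correlation). 5 of 24 members fell and 1 rose (13 and 1 adjusted over the list alone), with a median of -0.57. Cfi, the complement factor I protease, fell 12.6-fold from 0.21 ± 0.56 to -3.45 ± 0.19 (SD, n = 3 each; limma, adjusted p = 0.0018). Reg3g, an antimicrobial lectin, fell as well and was well above background on 1 of the 3 PGRA arrays. Without that array, PGRA replicate 2, it was at least 5.78-fold lower. The mucins Muc4 and Muc20 fell 7.50-fold and 2.53-fold, and Cd55, a complement inhibitor of the cell surface, 2.30-fold. Defb1, a defensin, rose 7.19-fold and was well above background on 2 of the 3 control arrays. A second Muc4 probe, at -4.54 in controls, was not well above background on any PGRA array and gives no exact difference. Muc4, Cd55 and Reg3g missed the threshold in 1, 3 and 5 of the 6 fits with an array left out (highest adjusted p = 0.112, Reg3g without control replicate 3).

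The Wnt pathway list fell (camera, adjusted p = 0.0138, and adjusted p = 0.636 with an estimated correlation), with 6 of 28 members lower and 1 higher (8 and 2 adjusted over the list alone) and a median of -0.29. Those that fell most were Lgr5, a receptor of R-spondins, 8.45-fold, Wnt7a, 2.73-fold, the secreted inhibitors Sfrp4 and Dkk3, 2.50-fold and 2.17-fold, and Axin2, a target of canonical Wnt signalling, 1.76-fold. Fzd6, a frizzled receptor, rose 2.18-fold from -0.25 ± 0.18 to 0.88 ± 0.11 (SD, n = 3 each; limma, adjusted p = 0.0066). The list's adjusted p was 0.0745 without control replicate 2 and 0.147 with array weights. Wnt7a, Lgr5 and Axin2 missed the threshold in 1, 1 and 2 of the 6 fits with an array left out, with adjusted p up to 0.0570 (Axin2 without PGRA replicate 2), and Axin2 did so with normexp (0.409).

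The lists that follow did not pass the list test and held changed members. With fry, the ion and water transport list (adjusted p = 0.0294) and the protease list (0.0306) passed, as did the cholesterol list with camera without control replicate 2 (0.0101) and the EGF and FGF list with array weights (0.0294). In that fit without control replicate 2, the cholesterol list had a camera adjusted p of 0.566 with an estimated correlation. Of 20 ion and water transport genes 5 fell and 2 rose (5 and 4 adjusted over the list alone; camera, adjusted p = 0.574). Aqp8, a water channel, fell 17.3-fold, Car12, a carbonic anhydrase, 11.1-fold, Slc26a6, an anion exchanger, 1.72-fold, and Slc9a2, a sodium-proton exchanger, at least 1.64-fold, besides Aqp5. Sgk1, a kinase that activates the epithelial sodium channel, rose 2.51-fold and Kcnq1, a potassium channel, 1.65-fold. Among 34 junction genes, Cldn10 and Gjb1 fell 2.32-fold and 1.74-fold while Cldn8 and Ocln rose 1.78-fold and 1.70-fold. In the prostaglandin list of 22, Pla2g10, a secreted phospholipase, rose 4.63-fold and Ptgs1 1.66-fold, and Hpgds fell 2.67-fold. In the retinoid list of 17, Lrat, which esterifies retinol, was at least 8.80-fold lower and Crabp2 higher by 0.58 ± 0.08 (SE) in log2 units. Of 13 steroid metabolism genes, Sult1d1, a sulfotransferase, fell 2.85-fold and Hsd17b2 at least 1.13-fold. Of 29 proteases and inhibitors, Mmp7, Pcsk6 and Ctsb fell 13.6-fold, 3.54-fold and 1.74-fold. Of 22 cytokines and chemokines, Ccl8 fell 3.67-fold and Cxcl5 at least 4.99-fold, and Il6 rose 6.46-fold. Fgf9 fell 4.56-fold among 24 EGF and FGF family genes. Mvk and Acaca, enzymes of cholesterol and fatty acid synthesis, rose 2.67-fold and 1.92-fold, and Adm rose 2.08-fold. Igfbp1, a decidual gene, was at least 1.42-fold lower, Ovgp1 2.62-fold lower and Ier3 2.76-fold lower. Ccdc113, of the ciliated cell list, fell with no bound above 1. Of these genes, only Car12, Aqp5, Slc9a2, Cldn10, Gjb1, Hpgds, Lrat, Sult1d1 and Pcsk6 passed in all 6 fits with an array left out. The highest adjusted p was 0.168, of Ccdc113 without control replicate 3. With normexp, Slc9a2, Hsd17b2, Cxcl5, Igfbp1 and Ccdc113 also missed the threshold (adjusted p = 0.404, 0.509, 0.200, 0.183 and 0.823). With slide column as a block Hsd17b2 (0.0858), Adm (0.0858), Crabp2 (0.0668), Ccdc113 (0.0970), Cldn8 (0.0526) and Ier3 (0.0506) missed it, and with quantile normalization Ctsb (0.0556), Hsd17b2 (0.0568) and Ccdc113 (0.0824) did. Mmp7 fell 21.0-fold without control replicate 1, and the bound of Cxcl5 was 3.02-fold without control replicate 2. Il6 was well above background on 2 of the 3 control arrays and Mmp7 on 2 of the 3 PGRA arrays.

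3 lists fell together with 0 or 1 members past the threshold, and each lost its call without control replicate 2. The cell division list had all 27 members below 0, a median of -0.56 and 0 members past the threshold (camera, adjusted p = 0.0018, and adjusted p = 0.849 with an estimated correlation). Mki67, a marker of dividing cells, stood at -0.46 ± 0.37 and Rrm2, a subunit of ribonucleotide reductase, at -0.94 ± 0.63 (SE). Without control replicate 2 Rrm2 stood at -0.18 and the list's median was -0.09 (adjusted p = 0.271). The respiratory chain list had 0 of 27 members past the threshold and a median of -0.17 (camera, adjusted p = 0.0018, 0.849 as adjusted p with an estimated correlation, and 0.0607 without control replicate 2). In the list of endoplasmic reticulum stress and secretory genes, 1 of 22 members fell, Trib3, 1.93-fold (camera, adjusted p = 0.0018, 0.849 as adjusted p with an estimated correlation, and 0.169 without control replicate 2). Trib3 missed the threshold in all 6 fits with an array left out (highest adjusted p = 0.104 without control replicate 3). With fry, which tests a list on its own, the 3 lists had adjusted p of 0.567, 0.273 and 0.490. Xbp1 stood at -0.97 ± 0.20 (SE) and did not pass.

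Among markers of other cell types, red blood cell genes shifted upward and macrophage and dendritic genes downward. Hbb-b2 rose 3.04-fold and Hba-a2 1.40-fold, 2 of 5 members (5 and 0 adjusted over the list alone; camera, adjusted p = 2.27e-05, and adjusted p = 0.526 with an estimated correlation). Hba-a1 stood at 0.65 ± 0.15 and Alas2 at 0.57 ± 0.14 (SE), not past the threshold. Hba-a2 missed it in 5 of the 6 fits with an array left out (highest adjusted p = 0.169 without PGRA replicate 2), with slide column as a block (0.114) and with quantile normalization (0.0556), and Hba-a1 passed without control replicate 2 (0.0361). The macrophage and dendritic list had 0 of 14 members past the threshold (8 lower adjusted over the list alone), a median of -0.40 and Mrc1, the mannose receptor, at -0.69 ± 0.16 (SE; camera, adjusted p = 7.62e-04, and adjusted p = 0.638 with an estimated correlation and 0.0912 with fry). Mrc1 passed without control replicate 2 (adjusted p = 0.0405). Stroma, smooth muscle, endothelium, lymphocyte, plasma cell, granulocyte and mesothelium lists had 0 members past the threshold. Without control replicate 2, 5 progesterone list members rose, 6 estrogen list members fell and 1 rose, 3 gland list members fell and 8 complement list members fell and 1 rose. Over the 6 fits with an array left out, 2 to 5 progesterone list members rose and 0 to 1 fell. In the estrogen list 3 to 6 fell and 1 to 2 rose, and in the gland list 2 to 4 fell and 0 to 1 rose. In the complement list 2 to 8 fell and 1 rose. In all, 12 of 39 lists passed with the preset correlation and 0 with the estimated one, and the other 27 had adjusted p from 0.164 to 0.982. The interferon list passed without control replicate 3 (0.0181) and without PGRA replicate 1 (3.38e-05). Median, mean and test direction differed in sign for the endothelium, mesothelium, junction, prostaglandin, steroid metabolism, cholesterol and glycolysis lists, none of which passed.

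**Figure D2:**
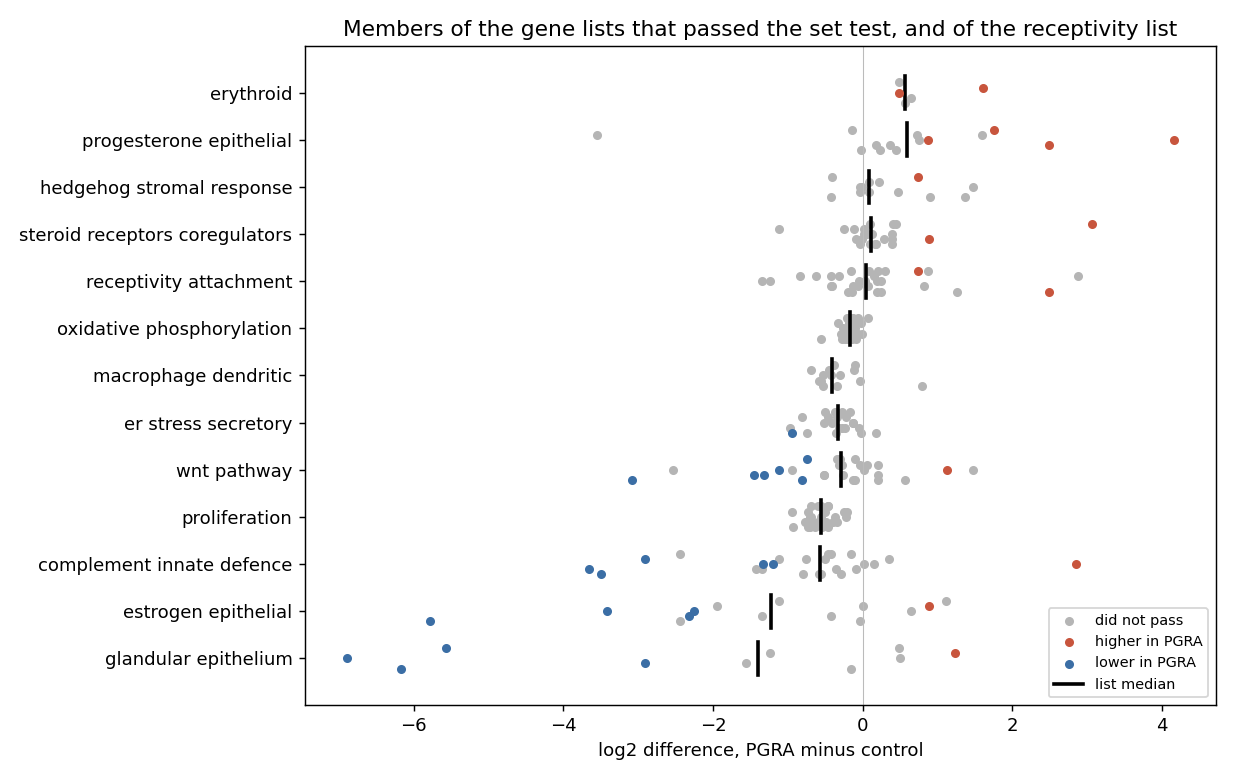
Log2 difference, PGRA minus control, of each tested member of the 12 lists that passed the camera test and of the receptivity list. Each point is 1 gene at its fitted value, coloured where it passed limma at adjusted p below 0.05, and the black bar is the list's median. The medians run from -1.40 for the gland list to 0.59 for the progesterone list, and the cell division list has all 27 points below 0.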

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

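The comparison of the E1A spike-ins was fixed before its values were seen, and the other tests of this part were chosen after the results were seen.

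Probes without a gene name, which enter the report only where unnamed probes are said to be included, also differed between the genotypes. Of 14484 such probes tested, 93 passed in limma after Benjamini-Hochberg adjustment, 45 higher and 48 lower in PGRA, and 1591 had an unadjusted p below 0.05. They were listed because they lie outside the genes of the main comparison.

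The 520 genes that differed were set against other divisions of the arrays. The 6 arrays can be split into 2 groups of 3 in 10 ways, too few for a share under 0.05. The real split gave 520 genes and was the 1 split with as many, and the highest of the others gave 0 in limma, with 223 to 732 genes at an unadjusted p below 0.05 against 2409. For the list test the real split gave 12 lists and the highest other split 11. Every other split puts both genotypes in each group, so a genotype difference widens the spread within groups and lowers the number of genes called. Part of that difference also stays between the groups of such a split. Neither count therefore serves as a comparison without a genotype difference, and chance is not excluded.

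Gland secretions fell on the PGRA arrays while other gland genes moved less or the other way. A smaller number of gland cells would lower all genes of those cells by about as much as Prss28, the smallest fall of Spink1, Prss28 and Prss29 at -5.57. The other 7 tested members of the gland list had a median of -0.15 with an SD of 1.45 and ran from -2.91 to 1.23. Sox9 stood at -2.91 and Cxcl15 at -1.56, while Foxa2 stood at 0.50 and Ttr at 1.23. Spink1, Prss28 and Prss29 were set apart as the list's largest falls, so the others had to fall less. The comparison therefore cannot decide on cell number. An effect of slide row or array brightness is argued against by the E1A spike-ins, whose group means differed by at most 0.125 log2 units over 7 spike-ins above background on all 6 arrays. A smaller loss of gland cells and an effect of the overexpressed receptor on gland gene expression, which the design names, both stay open, and the latter was not tested.

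Control replicate 2 stood apart from the other controls. Its difference from their mean had an SD over genes of 0.50, against 0.28 between the other 2 controls. The median of the cell division list lay 1.36 above them, at the 100th percentile of 10000 random lists of the same size and brightness. Members of that list moved together (estimated correlation 0.96) and those of random lists need not, so the percentile cannot decide on array quality. A spread of repeated spots of 5.43%, against 8.12% on control replicate 1, argues against poor spots only. A mislabelled array is argued against by Pgr, whose level minus that of the lowest PGRA array was -2.83. The decidualization list, of genes that stroma expresses after attachment or a decidual stimulus, lay 0.78 above the other controls by its median, also at the 100th percentile, with Il11 at 4.03, Wnt4 at 2.39 and Bmp2 at 1.74, while the luminal epithelium list lay at -0.64. The list of genes induced by tissue handling (0.57) was at the 100th percentile too, as were the endoplasmic reticulum (0.70) and cholesterol (0.55) lists. The interferon (-0.58) and junction (-0.33) lists lay at percentile 0, as did the luminal epithelium list. Estimated correlations between members of these lists ran from 0.12 (junction) to 0.90 (interferon), with 0.50 for decidualization and 0.36 for handling. Their percentiles therefore cannot decide either. Handling and a more advanced or decidualizing uterus among the 3 pooled mice both stay open as candidate explanations, and no biological explanation of the design applies to 1 pool.

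The Pgr probes disagreed, with differences of 3.06 and 0.06. Saturation of the second probe is argued against by the count of 0 saturated spots on the 6 arrays. Whether the second probe lies outside the transgene's transcript cannot be told apart from other reasons for its difference of 0.062, because probe sequences were not analysed here.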

How the results depend on the processing

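Slide column as a block (400 genes) and named with unnamed probes were chosen after seeing the data. The latter gave 587 of 29694 genes and unnamed probes, among them 413 of the 520 genes. The range over the other scalings, filters and variance models was 407 to 584 genes changed. Without the filter on dim probes 2482 genes passed, 1993 higher and 489 lower, and array weights gave 2542, 1160 and 1382. Their estimation stopped early, with weights from 0.165 for control replicate 2 to 8.75 for control replicate 3. The ordinary test gave 89, 43 and 46, and a threshold of 1.5-fold in addition 488, 194 and 294. With 1 array left out, 226 to 653 genes changed, 95 to 289 higher and 131 to 364 lower. Fewer arrays are one reason for the loss. All 520 genes kept their sign in every such fit. This was certain beforehand, because control and PGRA arrays did not overlap for any of the 520. Of the 1684 extra higher calls without the filter, 99.0% were on genes below background on all 6 arrays, where the floor of the signal may follow array brightness. The progesterone list (mean 0.71) had an adjusted p of 0.183 and the estrogen list (mean -1.32) of 0.204 with an estimated correlation, and the estrogen list 0.0995 (mean -0.86) without the filter. Over its other alternatives the adjusted p of the progesterone list reached 0.0144. Padi2, at 0.00, was -0.0084 with normexp, -0.30 with array weights, and -0.16, -0.21 and -0.04 without control replicate 2, PGRA replicate 1 and PGRA replicate 2, and up to 0.26 without PGRA replicate 3. Ccdc113 turned from -1.49 to 0.041 with normexp. The cause was not tested. No list call turned its direction. Of the named genes' results under alternatives, 1259 kept direction and side of the threshold, 165 lost the call, 5 gained it and 6 reversed. The labels number no replicates and pair no mice. The block pairs arrays by slide column, and their deviations from the group means correlated at 0.228, 0.192 and -0.0026 in columns 1 to 3. Control and PGRA arrays of different columns correlated at -0.237 to 0.038. Deviations from a mean of 3 arrays sum to 0, so these correlations depend on each other and do not establish a column effect. Blocks by slide or scan were not run, with 1 slide and 1 scan. Signal over background limits 74 of the 520 genes to bounds.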

Other observations

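The tests of this part were chosen after the results were seen, as were the genes it names.

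Solute carriers, the transporters of ions and small molecules, were found among the changed genes more often than other genes with all 6 arrays. Of 285 tested genes with an Slc symbol 24 changed (8.42%), 13 higher and 11 lower in PGRA. Slc24a4, a calcium exchanger, rose 20.5-fold, Slc7a4 by a log2 difference of 2.20 and Slc41a3 3.66-fold. Slc46a2 fell 26.5-fold, well above background on 2 of the 3 PGRA arrays, Slc39a8 and Slc39a4, both zinc importers, 5.42-fold and 3.88-fold, and Slc5a8, a monocarboxylate transporter, at least 8.79-fold (limma, Benjamini-Hochberg). Slc24a4 missed the threshold in 4 of the 6 fits with an array left out (highest adjusted p = 0.0699 without PGRA replicate 2) and its log2 difference was 3.58 without control replicate 2. The hypothesis that the family is over-represented was tested with one-sided Fisher's exact tests over 176 families of at least 10 tested genes with a shared symbol stem, and its adjusted p was 0.0082. The adjusted p was 1.62e-04 without control replicate 1, with 22 changed, and missed the threshold in the other 5 fits with an array left out. It was 0.0770 without control replicate 2 (24 changed), 0.626 without control replicate 3 (11) and 0.349, 0.126 and 0.302 without PGRA replicates 1 to 3 (12, 13 and 13). Genes of a family are not independent, and the test may be too small in p for that reason.

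Of 13 tested Wfdc genes, of the whey acidic protein family of secreted protease inhibitors, 4 changed, Wfdc12 by 16.9-fold, Wfdc15b by 7.09-fold and Wfdc15a by at least 2.75-fold upward and Wfdc17 by 2.19-fold downward, with an adjusted p of 0.0664 in the same tests, 0.0244 without control replicate 2, 0.0076 without PGRA replicate 1 and 0.626 to 0.985 in the other 4 fits. Wfdc12 was well above background on 2 of the 3 control arrays. With an array left out, Wfdc17 missed the threshold in 5 of the 6 fits (highest adjusted p = 0.108 without PGRA replicate 3), Wfdc12 in 3 (0.0671 without control replicate 3) and Wfdc15a in 1 (0.0512 without PGRA replicate 2). Other large changes outside all lists were those of Sctr, the secretin receptor, 20.8-fold higher, Gdpd3, a phospholipase, 20.5-fold higher, Gpx2, a glutathione peroxidase, 7.05-fold lower, and Pla2g7, a lipid hydrolase of plasma, 4.55-fold lower (limma). For Sctr, 1 of the 3 control arrays had no value, and the other 2 were well above background.

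Ereg, the EGF family ligand epiregulin, was at -7.45 and -7.54 on control replicates 1 and 3, at -2.37 on control replicate 2 and between -3.15 and -2.45 on the PGRA arrays. It did not pass in limma with all arrays (log2 difference 2.87 ± 1.36, SE) and was not well above background on control replicates 1 and 3, so that without control replicate 2 it was at least 5.53-fold higher in PGRA. Wnt4 likewise stood at 1.47 ± 0.69 (SE) with all arrays and at 2.27 without that replicate (adjusted p = 0.0327).

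Adipose genes varied between arrays of both groups. Adipoq, which encodes adiponectin, was at -0.08, -5.06 and -0.08 on control replicates 1 to 3 and at -5.37, -2.14 and 0.87 on PGRA replicates 1 to 3, and Fabp4, a fatty acid carrier, at 0.83, -1.69 and 1.41 and at -2.14, -0.66 and 2.06.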
